A study of Sus scrofa with 2 samples.

How the data were processed

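RNA from brain and liver of Rongchang pigs (Sus scrofa) was sequenced, and 1 library per tissue was analysed. Per the labels, frozen tissue was extracted with the reagent RNAiso Plus and libraries followed the standard Illumina protocol. The values used are raw counts per gene, deposited by the authors in 1 table with a brain column and a liver column. That these are counts was read from the values, which are whole numbers with different totals in the 2 libraries. Per the submitters' processing notes, reads were aligned with TopHat to the pig genome build Sscrofa10.2, which the notes also name susScr3. The version of TopHat, the program that counted reads and its strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes may be shared, and so may reads of near-identical copies. The table also holds a gene length deposited by the authors, a value in bp that was read here as the genomic span with introns, since it is too long for transcripts.

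The table has 21817 rows. Gene names came from the table for 7816 rows. Another 6594 rows were matched by gene number, 366 by transcript accession and 26 by a unique synonym to a RefSeq gene table of the assembly Sscrofa11.1, and 13 rows are mitochondrial. A match by accession or synonym was used only where the target symbol had no row of its own, and 7002 rows stayed unnamed. That reference table belongs to another assembly and was used for names and for gene order alone. Rows of 1 symbol were summed, which left 21444 genes, of which 360 had more than 1 row. Unnamed rows held 10.3% of brain counts and 6.34% of liver counts, and entered all totals and counts of genes.

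Counts were scaled with TMM in edgeR 4.0.16 (R 4.3.3), with no test from that package. The TMM factors were 1.47 for brain and 0.681 for liver, so that 1 CPM (scaled counts per 1000000) equals 34.9 counts in brain and 21.6 in liver. Scaled CPM therefore keep no fixed sum per library. They were not corrected for transcript length, so differences between genes within a library may also reflect length. The measure of difference is the log2 ratio, brain over liver, of scaled CPM with a pseudocount of 1, which understates the ratio of genes with low counts. Genes at 1 CPM or more in at least 1 library entered, and a gene was called higher in a tissue at 4-fold or more, a log2 ratio of 2 or of -2. With 1 library per tissue there is no test, no p-value and no replicate check, and the calls describe these 2 libraries. Folds of single genes were computed from scaled CPM without the pseudocount. Their 95% intervals are exact conditional binomial intervals, shares of counts have Wilson intervals, and both cover counting error only. Where a gene had 0 counts in a library, a floor of 3 counts was used, equal to 0.0858 CPM in brain and 0.139 CPM in liver, and the fold is a lower bound.

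In all, 52 gene lists with 985 symbols were fixed before the data were examined, along with the size rule, the rule for named genes and the other settings to be tried. For each list, the number of members at 4-fold or more in either tissue was counted. The median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from genes in 20 bins of mean expression. This placement describes the 2 libraries and is not a test of the tissues. Genes at 0 in 1 library, put at the floor, moved the median of 3 lists, by 0.119 at most on the log2 scale. Named genes have a symbol and follow a fixed rule. It takes the 10 highest genes of each library, the 12 highest and 12 lowest log2 ratios, and each top gene in the other library. From a described list it takes up to 4 members with the highest mean level, and members at 4-fold or more against the direction of its median. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

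The procedure was tested on simulated counts with the real depths, in which 200 genes were altered. Of 100 genes set 16-fold apart, 100 were called, and of 100 genes set 2-fold apart, 0 were called. Among 14998 unaltered genes, 0 were called. Both simulated libraries came from a shared mean profile with counting error only, and the altered genes were neither scarce nor among the most abundant. These calls were thus nearly fixed in advance by the 4-fold rule. They say nothing about variation between animals or about the different composition of the real libraries. Of 200 random lists of unaltered genes, 16 fell in the outer 5% of their matched random lists.

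Settings chosen in advance were pseudocounts of 0.1 and 5, no filter or a filter at 5 CPM, and folds of 2 and 8. Further settings were median-of-ratios scaling, plain library size, scaling without the 50 highest genes of either library, and the highest row per gene. Subtraction of carry-over and a count over named genes alone were added after the data were seen. A normalized column was foreseen as well and was not used here. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.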

Results

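Gene expression was compared between the brain and the liver of Rongchang pigs, a Chinese domestic breed, by RNA sequencing of 1 library per tissue. The labels give no age, sex or brain region, and do not say whether both pieces came from the same animal. The brain library held 23796843 counts and the liver library 31724498. There was no replicate check for any difference below, and all intervals cover counting error only, not the choice of scaling.

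The comparison asked which transcripts set the 2 tissues apart. In brain, the largest ratios belonged to genes of the neuronal cytoskeleton, of secretory granules and of myelin. STMN2, a microtubule regulator of neurons, reached 2035 CPM in brain against 0.463 in liver, a 4397-fold difference (95% interval 2391 to 9169). The neurofilament genes NEFM and NEFL had log2 ratios of 9.98 and 9.30, MAP1B, a microtubule-associated protein of neurons, had 9.25, and the myelin gene MOBP had 9.61. In liver, genes of secreted plasma proteins led. ALB, which encodes serum albumin, reached 276188 CPM against 44.7 in brain, a 6175-fold difference (5876 to 6493), and AFP, the albumin relative typical of fetal liver, was 7001-fold higher (5895 to 8379).

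Other genes among the 12 highest ratios are also known from neurons and their secretory granules. CHGA and CHGB, granins of secretory granules, had log2 ratios of 9.14 and 8.68. KIF5C, a kinesin motor of axonal transport, had 8.92, and GAP43, a growth cone protein, had 8.91. SNCB, a synuclein gene, was at 454 CPM in brain with 1 count in liver, so its fold of 9799 has a wide interval, from 1759 to 387076. The remaining lowest ratios were those of FETUIN (-12.20), the fibrinogen chain FGA (-12.07), haptoglobin HP (-12.00), transferrin TF (-11.68), AMBP (-11.65) and APOH (-11.64). They were followed by PZP (-11.55), the vitamin D binding protein GC (-11.51), the protease inhibitor SERPINA3-3 (-11.40) and plasminogen PLG (-11.11).

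**Figure D1:**
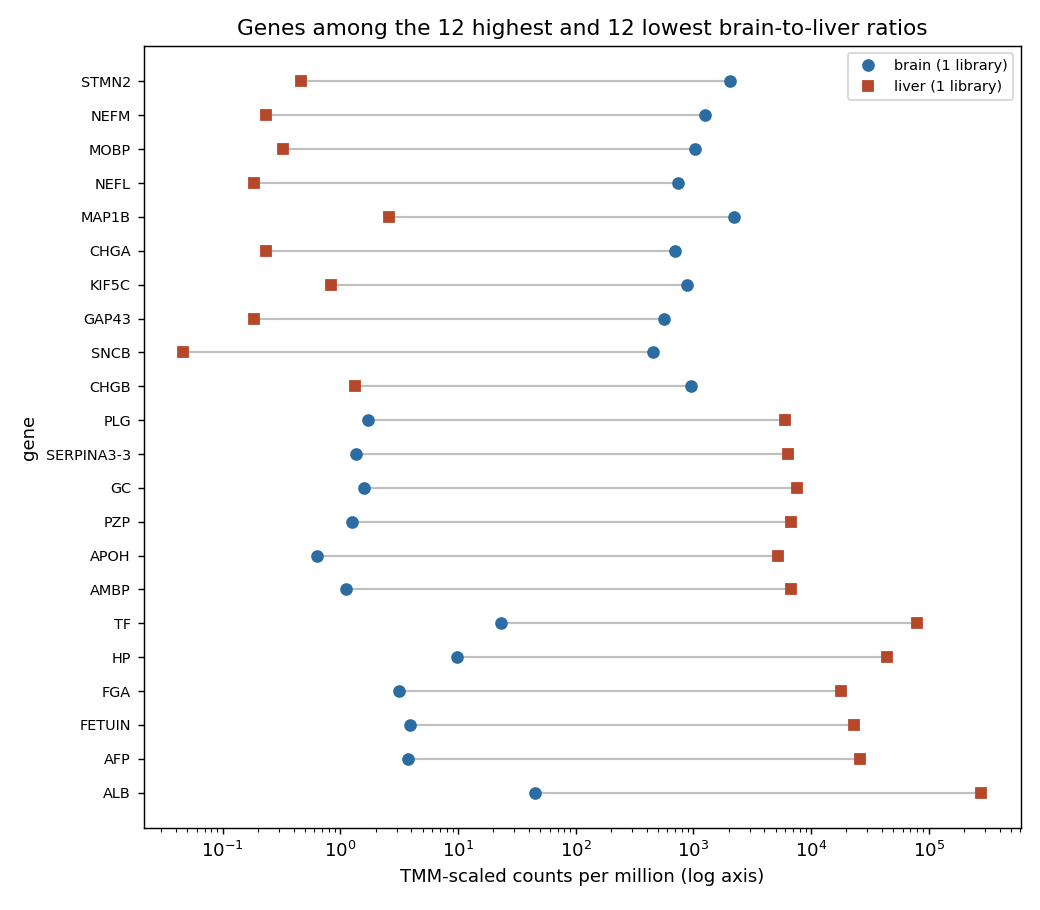
TMM-scaled CPM (log axis) of genes among the 12 highest and the 12 lowest brain-to-liver log2 ratios, with a circle for the brain library and a square for the liver library. STMN2 stands at 2035 in brain and 0.463 in liver, and ALB at 44.7 in brain and 276188 in liver.

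The liver library was concentrated in fewer transcripts. Its 10 most abundant genes took 35.9% of the counts (Wilson 95% interval 35.8 to 35.9), against 13.5% in brain (13.4 to 13.5), and ALB alone took 18.8%. After ALB, the named genes with the most liver counts were TF, HP, AFP, FETUIN, FGA, APOE, LGALS8, APOA1 and C3. In brain they included LGALS8, a galectin, then ACTB, EEF1A1, ESAM, HSP90AB1, CALM3, RPL13A, MAP1B and CLU. The LGALS8 row took 4.47% of brain counts and was 2.38-fold higher in brain (2.37 to 2.39). Its log2 ratio was 1.25, and 2.36 with plain library size, beyond 4-fold. Whether its reads come from that gene could not be checked without the older gene models. CALM3, a calmodulin gene, was 14.1-fold higher in brain, and the chaperone HSP90AB1 2.93-fold. The log2 ratio of HSP90AB1 was 1.55, and 2.66 with plain library size. ESAM, an endothelial adhesion molecule, was at 2916 CPM in brain and 6.94 in liver, with no row under the names of VSIG2 and NRGN, the next genes on 1 side of it in the reference table. Mitochondrially encoded genes took 9.47% of brain and 5.91% of liver counts.

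Several of the top liver genes were also well measured in brain. APOE, the lipid carrier that astrocytes also make, ranked 36 in brain at 1319 CPM and was 9.87-fold higher in liver (9.77 to 9.97). Its log2 ratio was -3.30, and -2.19 with plain library size. APOA1 was 47.6-fold and the complement component C3 335-fold higher in liver. ALB ranked 2838 in brain, with 1563 counts, equal to 0.0262% of its liver count. Of 54 other abundant genes of the liver lists, 15 had an interval holding this same percentage, 39 lay wholly above it and 0 wholly below it. Liver counts carried over at this percentage would limit folds toward liver to 6175, so the folds of ALB and AFP and others of like size are not exact if that occurred. Among the top brain genes, CLU had a log2 ratio of 0.08 and RPL13A of -0.02, and with the 3 other scalings they were at 0.33 to 1.19 and 0.22 to 1.09. EEF1A1, an elongation factor, was at -0.99, and at 0.12 with plain library size.

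Neuronal lists lay on the brain side. All 25 measured pan-neuronal genes were at 4-fold or more in brain (median log2 ratio 7.06), among them VSNL1 (5.07), CELF4 (5.57), SYT1 (7.14) and STMN2. All 26 synaptic vesicle and active zone genes did the same (median 5.46), including VAMP2 (4.55) and SYN1 (6.24). Of 17 glutamatergic genes, 15 were at 4-fold or more (median 4.91), among them the vesicular glutamate transporter SLC17A7 (8.17), DLG4 (6.05) and CAMK2B (7.39), while HOMER1 was at 0.32. Of 21 GABAergic genes, 16 were at 4-fold or more (median 4.74), with GABBR1 at 4.59, CALB2 at 5.43 and GAD1, which makes GABA, at 7.80. RELN in that list was at -0.92, and at 0.16 with plain library size. Of 18 voltage-gated and potassium channel genes, 15 reached 4-fold (median 3.87), including CACNA1A (6.56), with SCN8A at 1.84.

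Genes of monoamine, acetylcholine and neuropeptide neurons were sparser. Only 11 of the 25 with a row passed 1 CPM, and 5 of these were at 4-fold or more in brain (median 1.92), led by CARTPT (6.28), PENK (4.27) and CRH (3.93). DDC, a decarboxylase that liver also makes, went the other way at -4.01. Lists of brain regions differed. Of 10 forebrain genes, 8 were at 4-fold or more in brain (median 3.91), including MEF2C (3.98), LHX2 (3.18) and LAMP5 (7.53), with CUX2 at 1.11. For the cerebellum it was 8 of 13 (median 2.02), with PVALB at 3.62 and NEUROD1 at 2.01. ITPR1 was at -0.16, and at 0.08 to 0.92 with the 3 other scalings, and CA8 was at -0.21, and at 0.71 with plain library size and 0.18 without the 50 highest genes. For the striatum it was 2 of 7 (median 1.16), with FOXP1 at 1.05, PPP1R1B at 1.16, PDE10A at 0.90 and ISL1 at 1.56, and 5 of 7 with plain library size (median 2.19). In the thalamus, hypothalamus and midbrain list 1 of 5 was at 4-fold or more in brain (LEF1, 2.13) and 1 in liver (FOXA2, -5.29, chosen after its value was seen), and TCF7L2 was at -1.18. Of 17 brainstem and spinal Hox genes with a row, 5 passed 1 CPM and 0 reached 4-fold (median -1.17), with HOXA5 at -1.49. Of 9 pituitary genes with a row, 2 passed 1 CPM, including POMC (1.92), and 0 reached 4-fold, against 1 with plain library size.

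Glial lists also lay on the brain side, with exceptions. Of 18 astrocyte genes, 11 were at 4-fold or more in brain (median 3.58), including SPARCL1 (6.38) and, chosen after its value was seen, GFAP at 669 CPM (6.31). AGT, which encodes angiotensinogen, and ALDH1L1, a folate enzyme, were higher in liver at -4.07 and -4.92, as was FGFR3 at -2.45 (-1.50 with plain library size). NDRG2 was at -0.91, and at 0.20 with plain library size. Of 20 oligodendrocyte genes, 11 were at 4-fold or more in brain (median 2.69), including MBP (6.92) and CNP (2.69). TF, QDPR (-2.13) and MAL (-2.06) were at 4-fold or more in liver, the last pair below 4-fold with the 3 other scalings. Of 7 oligodendrocyte precursor genes, 3 reached 4-fold in brain (median 1.88), including PTPRZ1 (5.41) and BCAN, which had 0 liver counts and was at least 1571-fold higher in brain, while CSPG5 was at 0.73.

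The microglia and endothelial lists gave mixed results, while those of Kupffer cells and liver sinusoidal endothelium lay on the liver side. Of 16 microglia and macrophage genes, 2 were at 4-fold or more in brain, P2RY12 (2.87) and TREM2 (2.47), and 4 in liver, including C1QA (-3.21) and CD14 (-5.87, chosen after its value was seen). The median of this list was -0.50, and 0.57 with plain library size, with 2 at 4-fold or more in each tissue. Of 13 endothelial and pericyte genes, 3 were at 4-fold or more in brain, SLCO1C1 (5.75), RGS5 (2.85) and CLDN5 (2.74), and 4 in liver, including PECAM1 (-2.72), KDR (-3.03) and ABCB1 (-2.26). Their median was -0.27, and above 0 with plain library size (0.72) and without the 50 highest genes (0.19). With plain library size 4 were at 4-fold or more in brain and 0 in liver, with PECAM1 at -1.63, KDR at -1.95 and ABCB1 at -1.19. All 10 Kupffer cell genes were at 4-fold or more in liver (median -5.11, and 8 genes with plain library size), including CD5L (-7.90), MRC1 (-5.21) and HMOX1 (-4.60). For sinusoidal endothelium it was 10 of 11 genes (median -4.31), including STAB1 (-2.80), FCN2 (-7.12) and STAB2 (-5.88). Plain library size gave 9 genes, with STAB1 at -1.75.

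With plain library size, 5 stellate cell and matrix genes were at 4-fold or more in liver and 2 in brain (median -0.11), with COL3A1 at -1.27. With TMM, 6 of 17 were at 4-fold or more in liver (median -1.20), including fibronectin FN1 (-5.43) and COL3A1 (-2.36), while VIM was at 1.62. Of 9 cholangiocyte genes, 5 were (median -2.34, and 3 genes with plain library size), with SLC4A2 at -2.34 and ANXA4 at -3.11, while SPP1 was at 0.45 and KRT19 at 0.24, and at 1.51 and 1.28 with plain library size. Among 8 lymphocyte and antigen presentation genes, 3 were (median -1.70), CD8B (-8.46), SLA-DRA (-3.55) and SLA-DQA1 (-3.30). CD8B had 43811 liver counts while the T cell gene CD3E, chosen after its value was seen, had 57. FABP1, a fatty acid binding gene of liver 3 places from CD8B in the reference table, had no row, and whether the CD8B row holds its reads could not be checked. Of 5 choroid plexus and ependyma genes, TTR (-10.11) and FOLR1 (-3.07) were at 4-fold or more in liver and CCDC153 (3.40) in brain, with 1 in liver with plain library size. Of 5 erythroid genes, 2 were at 4-fold or more in liver (median -1.62, and 1 gene with plain library size), including SLC4A1 (-2.08), with HBB at -1.61. Of 5 genes of adjacent organs, 2 were at 4-fold or more in brain, LEP (3.67) and ACTA1 (3.22).

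**Figure D2:**
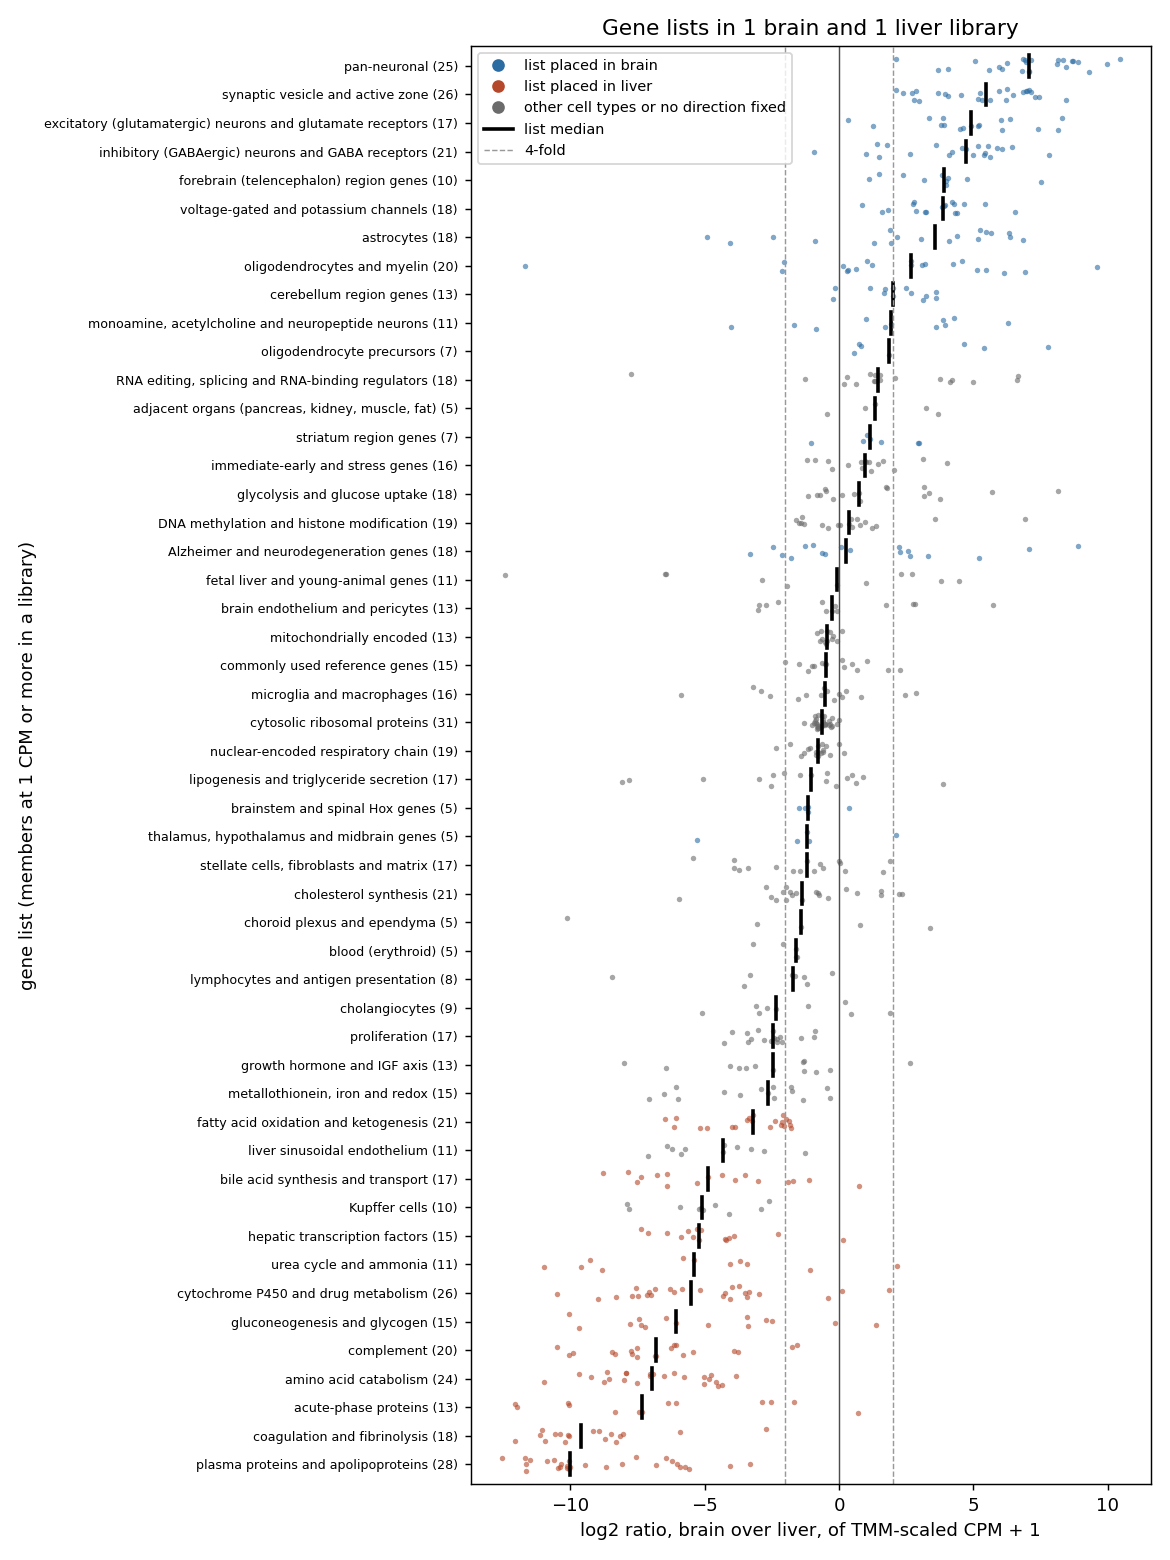
Log2 ratios, brain over liver, of scaled CPM plus 1 for the members of each gene list with at least 5 measured members (numbers in parentheses), in 1 brain and 1 liver library. Points are genes, black bars list medians and dashed lines 4-fold. Medians run from 7.06 for pan-neuronal genes to -10.03 for plasma proteins, and those between 0 and -0.77 lie above 0 with plain library size.

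Liver lists of secreted proteins lay far on the liver side. All 28 plasma protein and apolipoprotein genes were at 4-fold or more in liver (median -10.03), and together they took 29.2% of liver counts against 0.259% of brain counts. All 18 coagulation and fibrinolysis genes did so (median -9.60, and 17 genes with plain library size), with F5 at -2.73 (-1.62 with plain library size) and antithrombin SERPINC1 at -10.96. Of 13 acute-phase genes, 11 did (median -7.34), including ceruloplasmin CP (-8.34) and FGB (-10.10). Of 20 complement genes, 18 did (median -6.82), including C3, CFI (-6.08) and CFB (-6.84).

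Other lists of hepatocytes lay on the same side. All 24 amino acid catabolism genes were at 4-fold or more in liver (median -6.97), including HPD, of tyrosine breakdown, at -10.99, GNMT (-4.86) and GSTZ1 (-4.50). Of 15 gluconeogenesis and glycogen genes, 13 were (median -6.06, and 11 genes with plain library size), with FBP1 at -7.77, PYGL at -2.71 and UGP2 at -3.43. Plain library size put PYGL at -1.61. KHK, chosen after its value was seen, was at 1.37, and at 2.43 with plain library size. Of 26 cytochrome P450 and drug metabolism genes, 23 were (median -5.50), with CYP2C33 at -10.48 and EPHX1 at -3.37, while GSTA4 was at 0.11. CYP2C42, chosen after its value was seen, was at 1.88 in the direction of brain, and at 2.12 to 2.96 with the 3 other scalings. Of 11 urea cycle and ammonia genes, 9 were (median -5.38), with CPS1 at -10.96 and ASS1 at -9.28. GLUL, the glutamine synthetase that astrocytes also make, was at 2.17 in the direction of brain. Of 15 hepatic transcription factor genes, 14 were (median -5.20), including ATF5 (-7.10) and NR1I2 (-5.87), while NR1I3 was at 0.14. Of 17 bile acid genes, 13 were (median -4.88), including AKR1D1 (-8.80) and ACOX2 (-5.30). Of 21 fatty acid oxidation and ketogenesis genes, 17 were (median -3.21, and 11 genes with plain library size), including ACSL1 (-6.06) and ACADM (-5.16).

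Lipid synthesis was divided. Of 21 cholesterol synthesis genes, 2 were at 4-fold or more in brain, HMGCS1 (2.24) and SQLE (2.33), and 5 in liver (median -1.39). With plain library size it was 4 in brain and 1 in liver (median -0.37). FDPS (-0.77) and FDFT1 (-0.75) were above 0 with plain library size, at 0.33 and 0.35. Of 17 lipogenesis and triglyceride secretion genes, 7 were at 4-fold or more in liver (median -1.02), including ELOVL5 (-2.98), and 1 in brain, malic enzyme ME1 (3.86). The number in liver was 3 with plain library size. SCD was at 0.49, ACACA at 0.62 and FASN at -0.43, the last at 0.63 with plain library size and 0.01 without the 50 highest genes. Of 13 growth hormone and IGF genes, 7 were at 4-fold or more in liver (median -2.47), including IGFBP2 (-3.47) and IGF2 (-6.44), and the receptor gene IGF1R (2.65) in brain. Of 15 metallothionein, iron and redox genes, 10 were at 4-fold or more in liver (median -2.63, and 6 genes with plain library size), including FTL (-2.63), SELENOP (-6.51) and MT3 (-2.44), whose reads may be shared with other metallothioneins. FTH1 was at -0.33, and at 0.78 with plain library size and 0.13 without the 50 highest genes.

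Genes of cell division lay on the liver side. Of 17 proliferation genes, 14 were at 4-fold or more in liver (median -2.46), including TOP2A (-3.39), CENPF (-2.77) and PCNA (-2.20). Plain library size gave 6 of 17 (median -1.63). MKI67 was at -0.93, and at 0.15 with plain library size. In the list of fetal liver and young-animal genes, 4 of 11 were at 4-fold or more in brain, MEG3 (4.46), SOX11 (3.78), DCX (2.73) and SOX4 (2.32). A further 4 were in liver, AFP, IGF2 (-6.44), GPC3 (-6.48) and, chosen after its value was seen, IGF2BP1 (-2.85). The number in liver was 3 with plain library size, with IGF2BP1 at -1.98. Liver held 9.43 AFP counts per 100 ALB counts.

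Of 18 glycolysis and glucose uptake genes, 6 were at 4-fold or more in brain and 0 in liver (median 0.76), the 6 being ENO2 (8.14), ALDOC (5.69), PFKM (3.77), PKM (3.34), HK1 (3.16) and PFKP (3.15), all chosen after their values were seen. GAPDH was at 0.12 and TPI1 at 0.76, while LDHB (-0.52) and PGAM1 (-0.23) were above 0 with plain library size, at 0.58 and 0.88, and PGAM1 with every other scaling run. Of 18 RNA-binding regulators, 7 were at 4-fold or more in brain (median 1.44) and 1 in liver, A1CF (-7.74), with ELAVL1 at -1.27, CELF5 at 1.53 and SRRM4 at 1.32. The number in brain was 13 with plain library size (median 2.50). Of 19 genes of DNA methylation and histone modification, 2 were in brain, CHD5 (6.91) and HDAC9 (3.57), both chosen after their values were seen, and 0 in liver (median 0.38), and 4 in brain with plain library size. Of 16 immediate-early and stress genes, 3 were in brain, HSPH1 (3.12) and, chosen after their values were seen, EGR1 (4.02) and NPAS4 (2.06), and 0 in liver (median 0.97), with HSP90AA1 at 0.96. Plain library size put 8 in brain (median 1.95). Of 18 Alzheimer and neurodegeneration genes, 8 were in brain (median 0.25), including APP (3.30), and 3 in liver, APOE, PSEN2 (-2.47) and GRN (-2.14). Plain library size gave 8 in brain and 1 in liver (median 1.35), with PSEN2 at -1.40 and GRN at -1.05, and GRN was below 4-fold with the 3 other scalings. The Y-linked list had 1 measured gene, EIF1AY at -1.27, which may share reads with an X-linked copy.

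Genes that every cell uses differed little, and their direction depended on the scaling. The 31 cytosolic ribosomal protein genes had a median of -0.65 with 0 at 4-fold, and 0.46 with plain library size. For the 13 mitochondrially encoded genes these values were -0.45 and 0.66, and 0.01 without the 50 highest genes. The 19 nuclear-encoded respiratory chain genes had a median of -0.77, with SDHC, chosen after its value was seen, at -2.33. With plain library size the median was 0.33 and SDHC was at -1.23. The 15 common reference genes had a median of -0.50, and 0.60 with plain library size, with YWHAZ at 2.28 and, chosen after its value was seen, GUSB at -2.01 (-0.94 with plain library size).

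In total, 15572 genes passed 1 CPM in at least 1 library. Of these, 2278 (14.6%) were at 4-fold or more in brain, 1767 (11.3%) in liver and 11527 in neither, and 48.1% lay within 2-fold. Brain accounted for 56.3% of the calls, against 80.0% with plain library size and 67.9% without the 50 highest genes. In the latter the pseudocount also weighed less and 16480 genes passed 1 CPM. Plain library size and scaling without the 50 highest genes moved the median log2 ratio of all genes toward brain by 0.97 and 0.45. Median-of-ratios scaling moved it by 0.22. The following numbers are with TMM. Genes at 1 CPM or more numbered 14288 in brain and 13086 in liver, 11802 of them in both, 2486 in brain alone and 1284 in liver alone. Among matched random lists, the medians of 8 of the 15 lists placed in brain lay above all 10000. These were the pan-neuronal, synaptic, glutamatergic, GABAergic, channel, forebrain, astrocyte and oligodendrocyte lists. The medians of all 11 lists placed in liver lay below all 10000, as did those of the Kupffer, sinusoidal, proliferation and metallothionein lists.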

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

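Carry-over subtraction and the count over named genes alone were chosen after the data were seen. No paired analysis was possible because there is 1 library per tissue. For the same reason no library could be left out, and a normalized column was not used. Genes at 4-fold or more in brain (2278) and in liver (1767) stayed within 1.5 times with a pseudocount of 0.1, a filter at 5 CPM, median-of-ratios scaling, scaling without the 50 highest genes, the highest row per gene, carry-over subtraction (2280 and 1767) and named genes alone (1795 and 1454). They were 1230 and 1117 with a pseudocount of 5, and 3819 and 953 with plain library size. They were 4284 and 3803 at 2-fold, and 1330 and 887 at 8-fold. Genes detected in both tissues were 7822 at 5 CPM and 18528 at any count above 0, and genes detected in liver alone 794 at any count above 0. The share of the 10 most abundant genes was 9.95% in brain and 37.2% in liver without mitochondrial genes, and 9.97% and 39.7% over named genes alone. Leaving out the filter at 1 CPM says nothing about stability, since with a pseudocount of 1 a 4-fold call needs at least 3 CPM. The highest row per gene could alter the counts of only the 360 genes with more than 1 row, and named genes alone are a subset of the same calls. Carry-over subtraction took 0.0262% of each liver count from brain and 0.0141% of each brain count from liver. These settings therefore say little about stability. Of 260 list counts under alternatives other than the filter, 223 stayed within 1.5 times, and those with the highest row per gene had little room to move. Of 283 list members at 4-fold or more in liver, 54 fell below 4-fold with plain library size, 21 without the 50 highest genes and 13 with median of ratios, 12 of them with all 3, among them QDPR, MAL, GRN, PCNA, SLC4A1 and GUSB. Of 179 in brain, 0 did, but these scalings moved nearly all ratios toward brain, so few brain calls could be lost. With plain library size, the number at 4-fold or more in liver was 2 for microglia, 0 for endothelium, 1 for choroid plexus, 11 for fatty acid oxidation, 1 for cholesterol synthesis, 3 for lipogenesis, 3 for cholangiocytes, 1 for erythroid genes, 6 for proliferation, 0 for the respiratory chain, 0 for reference genes and 6 for metallothionein, iron and redox. The number in brain was 5 for striatum, 1 for pituitary hormones, 8 for immediate-early genes, 13 for RNA-binding regulators and 4 for DNA methylation and histone modification. With median-of-ratios scaling it was 1 for pituitary hormones in brain, and 1 for erythroid and 0 for reference genes in liver. With a pseudocount of 0.1 it was 8 for monoamine and peptide neurons, 1 for pituitary hormones and 5 for immediate-early genes in brain, and 7 for lymphocytes in liver. At 2-fold it was 8 for monoamine and peptide neurons, 5 for striatum, 1 for pituitary hormones, 7 for immediate-early genes, 13 for RNA-binding regulators and 4 for DNA methylation in brain. At 2-fold in liver it was 11 for cholesterol synthesis, 7 for lymphocytes, 5 for erythroid genes, 2 for ribosomal proteins, 6 for the respiratory chain, 3 for reference genes and 1 for the Y-linked list. Among the 36 genes named for abundance or ratio, EEF1A1 and RPL13A crossed 0 with plain library size and RPL13A with median of ratios, none of them at 4-fold in either tissue. For these 36 genes, a pseudocount of 0.1, median of ratios and plain library size were compared with the counting interval. The ratio moved beyond that interval in 60 comparisons and stayed within it in 48. Plain library size moved the ratios of all 15572 measured genes toward brain, by 0.253 to 1.11, as did median of ratios, by 0.0604 to 0.245. Scaling without the 50 highest genes moved 14776 toward brain and 796 toward liver. With that scaling 1 CPM equals 17.9 counts in brain and 15.2 in liver, so the pseudocount weighed less and 16480 genes passed 1 CPM. Its values thus mix the scaling with effects of the pseudocount and the filter. With TMM, depth limits genes near 1 CPM, equal to 34.9 counts in brain and 21.6 in liver.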

Other observations

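The tests on liver transcripts in brain and on ESAM, and the gene pairs described next, were chosen after the values were seen. Among 8 pairs of related genes that serve one function, 6 had the first gene at 4-fold or more in brain and 5 had the other at 4-fold or more in liver, and 7 and 4 with plain library size. For glycogen phosphorylase, PYGB was at 73.4 CPM in brain and 0.602 in liver, while PYGL was at 45.7 and 304. For glucose transport, SLC2A3 was at 39.7 CPM in brain and 10.7 in liver, while SLC2A2 was at 0.0286 and 151. For glycogen synthase, GYS2 had a log2 ratio of -7.46, while GYS1 was at -0.18, and at 0.05 to 0.86 with the 3 other scalings.

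Fatty acid activation and the aspartate-glutamate carrier were divided as well. ACSL6 had a log2 ratio of 4.65 and ACSL1 of -6.06. The carrier SLC25A12 was at 2.26, and SLC25A13, which also serves the urea cycle, at -3.70. In 2 of the 8 pairs the first gene was below the other in brain, in CPM not corrected for transcript length. These were CPT1C and CPT1A of carnitine palmitoyltransferase, at 53.7 and 56.9 CPM in brain with log2 ratios of 2.67 and -1.87, and the kinesins KIF5A and KIF5B, at 151 and 222 CPM with log2 ratios of 7.06 and 0.87.

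Genes higher in brain had longer genomic spans, in a comparison planned before the spans were computed. The median span was 35.3 kb over 2278 genes higher in brain, 17.6 kb over 1767 genes higher in liver and 21.2 kb over the other measured genes. Spans over 100 kb made up 25.5% of the former and 6.34% of the latter. The ratio of the medians was 2.01, and 2.24 with 1448 genes per side matched on mean level (2.01 to 2.55 over 1000 draws from the same genes). The mean level over both libraries therefore does not account for it. Level in the tissue of the call was not matched, and calls under other scalings were not tried. The hypothesis that long genes are favoured in brain was not tested here in other animals, and unspliced reads, which may add counts to long genes, were not examined.

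Transcripts of the liver lists were found in the brain library. Counts of the liver library carried over at 1 rate cannot be the whole source. The ALB percentage of 0.0262% is then the highest rate possible. Of 54 other liver-list genes with at least 20000 liver counts, 72.2% (39 genes) had an exact Poisson interval wholly above it. The highest was APOE at 16.4%, a gene that astrocytes also make. The median over the 54 genes was 0.0638%, and some of those above lay close to ALB, such as TF at 0.0473% and HP at 0.0359%. As a part of the source, carry-over requires that abundant liver genes do not fall below its rate, and 0% of the intervals lay wholly below the ALB percentage. ALB had the lowest log2 ratio of the measured genes with a symbol, which made this outcome likely in advance. The other 15 intervals (27.8%) held it, among them those of AMBP (0.0265%), FGA (0.0286%) and APOC3 (0.0247%). For these 15 genes, transcription in the brain piece alone cannot be told apart from carry-over, since values near 1 rate are what carry-over would give and low transcription may give them as well. Both labels carry the same lane and barcode. In the other direction, the liver counts of STMN2 were 0.0141% of its brain counts. Of 13 other abundant brain-list genes, 3 had intervals holding this percentage and 10 lay above it (median 0.688%). STMN2 had the highest ratio toward brain, so other genes were likely to lie above it. The 13 genes also include APOE (610%) and CLU (58.5%), abundant in liver, so this count cannot show whether counts were carried over toward liver. With carry-over at the ALB percentage, the fold toward liver would be limited to 6175, so folds near it may be lower bounds and their order may carry no information.

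The ESAM row, 101896 counts in brain and 150 in liver, stands apart from other endothelial genes. The log2 ratios of the 13 other endothelial and pericyte markers ran from -3.03 to 5.75, below the 8.52 of ESAM. Their median was -0.27 (0.72 with plain library size). These ratios cannot decide whether the brain piece was rich in endothelium, since the liver has endothelium of its own. In brain, ESAM was at 2916 CPM, and the highest of the 13 markers, SLCO1C1, was at 72.5 CPM. A candidate explanation is that reads of NRGN, a neuronal gene 2 places away in the reference table, were entered under ESAM. The counts analysed here hold 0 rows under that name or under VSIG2, the gene in between, which leaves this open, as a row can be absent for other reasons. Whether endothelium accounts for the ESAM value was not settled, and no other biological explanation of it was tested.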
